A study of Danio rerio with 6 samples.

How the data were processed

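The data are RNA-seq counts from 6 libraries of cells sorted by fluorescence from zebrafish larvae, 3 of GFP-positive intestinal epithelial cells (IEC) and 3 of GFP- and dextran-positive lysosome rich enterocytes (LRE). Per the labels' protocols, larvae were gavaged at 5 days after fertilization with 1 to 2 nl of dextran at 2.5 mg/ml and dissociated 24 hours later with trypsin, EDTA and collagenase. Total RNA was purified with a micro-scale column kit, and libraries came from a Clontech kit for ultra low inputs. Reads were aligned with HISAT2 and counted with HTSeq on the GRCz10 build, per the submitters' processing notes; versions, the annotation release, and HTSeq's strand and overlap modes are not given in the sources used here. The deposited values are whole-number counts per gene, 1 file per library, with no normalization by the authors found in them. Amplification from low inputs can widen the spread between libraries, and reads shared between near-identical genes may have been dropped or split, so paralogs are uncertain. Reads of overlapping and antisense genes cannot be told apart.

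Each file held 35117 Ensembl gene IDs, of which 28129 had at least 1 read in some library, and 0 entries that named no gene. Symbols came from a table that pairs Ensembl IDs with names and covered 27000 IDs. Many of its symbols are written in capitals without the letter of a zebrafish paralog, so a listed symbol was matched by exact spelling first and otherwise without regard to case, a choice made once that table was seen. Of 847 listed symbols, 628 matched and 219 did not. A wider rule that also dropped paralog letters and numbers matched 141 more and was run as an alternative. Coordinates were not used, since no genome of the authors' build was used here.

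Groups came from the sample titles. Total counts ranged from 39590129 to 53250871, and a count of 0 in a library allows up to 3 counts. Such floors and all binomial intervals (95%, Wilson for shares) cover counting error only, since no molecular identifiers are named in the labels. Within groups the libraries correlated at 0.908 to 0.962 and between groups at 0.847 to 0.919 (Pearson's r across genes of log2 CPM, where genes are not independent replicates), and no pair differed by as little as sampling noise.

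The groups were compared with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit and F test, TMM factors from 0.692 to 1.40). Genes were filtered by filterByExpr at its defaults (minimum count 10, minimum total 15), which left 20979. The Benjamini-Hochberg adjusted p had to be under 0.05, and TREAT used a fold of 2. The SE of a log2 fold change is its size divided by the root of F. CPM values are counts divided by the TMM-scaled totals, and the ratios with counting intervals use the same totals; shares of a library in percent use the plain totals. Gene lists, 16 functional, 4 of quality and 13 of cell type markers, were tested with camera of limma 3.58.1 (preset correlation 0.01, lists of at least 5 tested members), then with an estimated correlation and with fry. The lists were written from textbook knowledge of the gut, and none was chosen on these libraries. Counts adjusted over a list alone use the Benjamini-Hochberg method within that list, with no correction across lists. They were not in the plan fixed in advance. Lists, test, filter, thresholds, alternatives and the rule for named genes were fixed before the data were examined.

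That rule took cldn15la, cubn, amn, dab2, lrp2a and lrp2b whatever their values. It took the 6 genes with the largest and the 6 with the smallest log2 fold change among those that passed at a mean of at least 10 CPM with groups that did not overlap. For each functional and quality list it took up to 3 passing members with the smallest p, and all passing intestinal transcription factors. For each marker list with a passing member it took the passing member with the smallest p and the most abundant one. The 3 genes with a symbol that were most abundant in each group completed the 56 named genes. Other genes are said to be picked out after their values were seen; 1 further group picked that way is not reported here.

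The replicate numbers are shared between the groups, and the labels do not say what a number marks. The deviations from the group means correlated at 0.217, 0.238 and 0.188 (Pearson's r across genes) in the pairs of equal number, and at -0.194 to 0.0136 in the other pairs, so the numbers were taken to pair the libraries, from the data alone. Deviations cancel within a group, so positive values in some pairs force lower values in others. With 3 libraries per group, such a match could also arise by chance. The fit with the number as a block was an alternative. Others were RLE and upper-quartile factors, scaling by totals alone, no filter, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma voom, thinning to the smallest total, and leaving out each library in turn. Chosen after seeing the data were a fit without mitochondrial genes and the most abundant gene, a fit without both libraries numbered 1, a robust fit, and the wider symbol matching.

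The procedure was tested on simulated counts for the LRE and IEC comparison with 20979 genes, of which 200 were changed. It recovered 2% of genes changed 2-fold, 48% at 4-fold, 94% at 16-fold and 100% at 64-fold, with 6 of 128 calls among unchanged genes. Tables were prepared with Python 3.11.15 and pandas 2.3.3.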

Results

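Gene expression was measured by RNA sequencing in 2 populations of intestinal cells sorted from zebrafish larvae of the EK strain at 6 days after fertilization. The larvae had received Alexa Fluor 568 dextran, a fluorescent sugar polymer, into the gut lumen by gavage 24 hours earlier. Cells positive for a cldn15la-GFP reporter, which marks intestinal epithelium, formed the group of intestinal epithelial cells (IEC, n = 3 libraries). Cells positive for both GFP and the dextran formed the group of lysosome rich enterocytes (LRE, n = 3 libraries), enterocytes that take up luminal material and carry large lysosomes. The labels do not say whether dextran-positive cells were kept out of the IEC gate, so each value holds for the populations as sorted. Total counts assigned to genes lay between 39590129 and 52824999 in the IEC libraries and between 42321698 and 53250871 in the LRE libraries. Nothing in the labels says that the numbered libraries came from separate pools of larvae, so p-values measure only the spread between these libraries, which may be technical.

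LRE library 1 stood apart from the other libraries. It held at least 1 read in 19396 genes, against 22974 to 25610 in the others. Its 10 most abundant genes took 42.99% of all counts (95% Wilson interval 42.974 to 43.004%). Mitochondrially encoded genes with a symbol that begins with MT took 21.69% (21.677 to 21.702%). These intervals cover counting error only. On the first principal component (44.5% of the variance) its score was 240.6, against scores from -76.4 to -4.67 in the other 5 libraries. The second component (29.7%) gave scores from 35.1 to 123.6 in the IEC libraries, and of 37.0, -85.0 and -149.5 in the LRE libraries 1, 2 and 3. Mitochondrial genes with an MT symbol took 5.87% ± 2.49 of the counts in IEC and 13.1% ± 7.89 in LRE (mean ± SD, n = 3 each). Any mitochondrial genes without a symbol are not in these shares. The most abundant gene of each library had no symbol and took from 5.19% (IEC 3) to 19.34% (LRE 1) of the counts.

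The comparison of LRE with IEC asked which transcripts distinguish the enterocytes that had taken up the tracer from the GFP-positive cells sorted as IEC. LRE libraries held far more mRNA of the cubilin and amnionless endocytic receptor and its adaptor Dab2, and more of many lysosomal proteases and glycosidases and of several brush border peptidases and transporters of amino acids and bile acids. They held less mRNA of several fat-handling genes, FABP2, apoea and apoc2 among them, and of the hormone genes gip and ghrl. Each of these named calls ended when some single libraries were left out. The summed abundance of the fat absorption list was about equal in the groups. Of 20979 genes tested, 483 were higher and 191 lower in LRE (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). A change beyond 2-fold passed for 153 higher and 33 lower genes (TREAT). Of those counts, the higher fell to 89 without IEC 1, 55 without IEC 2, 66 without IEC 3 and 67 without LRE 3, and the lower to 3, 10, 6 and 6; without LRE 1, 75 were lower. TREAT counts were also 228 higher and 60 lower with the replicate block, 49 higher with scaling by totals alone and 68 lower without a filter. The unadjusted p was under 0.05 for 3562 genes, and the biological coefficient of variation was 0.651. All 3 LRE values lay on the same side of all 3 IEC values in 26.8% of tested genes, where chance gives 10%, and in all 674 genes that passed.

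The counts of genes moved with the libraries and the method. No gene that passed in the main fit passed in the opposite direction in another fit. The fits share most or all of their libraries, so this could hardly turn out otherwise and says little about direction in new libraries. Of the genes that passed, 71.7% were higher in LRE, against 58.0% with DESeq2 (1316 higher, 952 lower) and 42.9% when libraries were scaled by their totals alone (137 higher, 182 lower). That scaling moved the median log2 fold change of all genes by -0.40. With the replicate number as a block, 789 genes were higher and 367 lower, and limma voom gave 606 and 290. Without both libraries numbered 1, an alternative chosen after seeing the data, 251 were higher and 144 lower (TREAT 28 and 15). Leaving out 1 library gave 258 higher and 65 lower genes without IEC 1, 166 and 57 without IEC 2, and 146 and 28 without IEC 3. It gave 287 and 79 without LRE 2 and 168 and 47 without LRE 3, while 419 genes were higher and 261 lower without LRE 1. Of the 33 gene lists fixed in advance, 17 were higher and 7 lower in LRE against all other genes (camera, inter-gene correlation preset at 0.01). None of the 24 passed with an estimated correlation. Those estimates ran from 0.0087 (autophagy regulators) to 0.978 (mitochondrial transcripts) and were 0.371 for the lysosomal hydrolases. Other splits of the 6 libraries into groups of 3 passed up to 19 lists at the preset. A list called higher or lower at the preset is therefore weak evidence on its own. With fry, which asks whether the genes of a list move on balance in 1 direction, 10 lists were higher and 3 lower. The 11 that fry did not keep were the lists of dietary fat absorption, xenobiotic metabolism, the microvillus, mitochondrial transcripts, best4 cells, fibroblasts, muscle, hepatocytes, neurons, leukocytes and exocrine pancreas.

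Components of the apical endocytic receptor showed some of the largest differences. CUBN (ENSDARG00000087013), which encodes the ligand-binding receptor cubilin, had an abundance of 4.15 ± 1.41 CPM (counts scaled by TMM-adjusted library totals) in IEC and 514 ± 138 in LRE (mean ± SD, n = 3 each). Its log2 fold change was 6.96 ± 0.45 (SE, adjusted p = 0.0018). Its membrane partner amn rose by 6.64 ± 0.60 (adjusted p = 0.0020), the clathrin adaptor dab2 by 5.58 ± 0.43 (adjusted p = 0.0018) and the megalin gene lrp2b by 5.197 ± 0.51 (adjusted p = 0.0025). LRPAP1, a chaperone of megalin-type receptors, rose from 20.6 ± 2.12 to 276 ± 36.3 CPM (log2 fold change 3.74 ± 0.28, adjusted p = 0.0018). These 5 genes passed in every leave-out of 1 library. Of the 25 tested members of the list of cubilin and megalin endocytic machinery, 7 were higher and none lower, also when adjusted over the list alone, and 18 did not pass. The other 2 higher members, picked out after their values were seen, were the endosomal GTPases RAB5C (1.56) and RAB11A (1.40). The list was higher as a group (adjusted p = 4.4e-11, adjusted p = 0.0895 with an estimated correlation). Its median log2 fold change was 0.30 and its mean 1.301, and the median was 0.49 without IEC 2 and -0.12 with scaling by totals alone, which lies above the shift of all genes. The sorting marker cldn15la itself had 3845 ± 1261 CPM in IEC and 2825 ± 213 in LRE, and did not pass (log2 fold change -0.44 ± 0.40, adjusted p = 0.640). The symbol lrp2a was not among the names used, many of which lack the paralog letter, so a value for that gene is not given.

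Lysosomal enzymes were higher in LRE as a broad group. Of 48 tested lysosomal hydrolases, 27 were higher and none lower, or 32 higher and none lower when adjusted over the list alone. The median log2 fold change was 2.11 (adjusted p = 4.7e-48, adjusted p = 0.151 with an estimated correlation). The summed abundance of the list went from 2301 to 3047 CPM in the IEC libraries to between 24706 and 51869 CPM in the LRE libraries. Among those with the smallest p were the protease genes SCPEP1 (4.82 ± 0.44, adjusted p = 0.0020) and CTSH (5.09 ± 0.48, adjusted p = 0.0024), and GALC (ENSDARG00000037064), which encodes galactosylceramidase (3.78 ± 0.33, adjusted p = 0.0020). CTSH, or cathepsin H, went from 67.3 ± 4.27 to 2287 ± 930 CPM. Picked out after their values were seen, ctsl.1 went from 284 ± 103 to 17623 ± 6032 CPM and LGMN, the protease legumain, from 147 ± 26.4 to 6730 ± 2981 CPM. Cathepsin L genes have close copies in this genome, so reads may be split between them.

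Membrane proteins of the lysosome were higher as a list; whether they differed by less than the hydrolases was not tested. Of 24 tested lysosomal membrane proteins and subunits of the proton pump, 6 were higher and none lower, or 14 higher and 1 lower when adjusted over the list alone. The list was higher (median 1.03, adjusted p = 3.6e-09, adjusted p = 0.236 with an estimated correlation), while the log2 ratios of its summed abundance were 0.02, 0.32 and 0.79 in the pairs numbered 1, 2 and 3. Its higher members included the cystine exporter CTNS (2.45 ± 0.35, adjusted p = 0.0111), scarb2a (1.88 ± 0.33, adjusted p = 0.0218) and LAMP2 (1.73 ± 0.32, adjusted p = 0.0262). In the list of regulators of autophagy and lysosome biogenesis, 1 of 29 members passed, or 4 when adjusted over the list alone. It was TFEB, a transcription factor that activates lysosomal genes, which rose from 4.27 ± 1.93 to 76.1 ± 35.1 CPM (4.15 ± 0.50, adjusted p = 0.0049). That list was higher (median 0.32, adjusted p = 0.0147, adjusted p = 0.236 with an estimated correlation), but lost its call without IEC 3 (0.0517, median 0.17), without LRE 1 (0.0785), without both libraries numbered 1 (0.0737, median 0.29), and with scaling by totals alone (0.0737, median -0.07). The calls of CTNS, scarb2a and LAMP2 ended with scaling by totals alone (adjusted p = 0.0683, 0.195 and 0.150). They also ended without LRE 3 for CTNS (0.0509), without IEC 1, IEC 3, LRE 2 or LRE 3 for scarb2a (up to 0.111), and without any 1 of the 6 libraries for LAMP2 (up to 0.143).

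Peptidases of the brush border were higher in LRE. Of 18 tested members, 7 were higher and 1 lower, or 8 and 1 when adjusted over the list alone (median 1.01, adjusted p = 3.6e-09, adjusted p = 0.236 with an estimated correlation). ENPEP, which encodes aminopeptidase A, went from 41.0 ± 14.2 to 534 ± 114 CPM (3.70 ± 0.38, adjusted p = 0.0029). The glutamate carboxypeptidase genes NAALAD2 (4.09 ± 0.40, adjusted p = 0.0025) and naaladl1 (3.60 ± 0.39, adjusted p = 0.0032) rose in a similar range. MEP1B, which encodes a meprin subunit, is the symbol of 2 genes, of which ENSDARG00000040683 was higher (2.74 ± 0.43, adjusted p = 0.0148) and ENSDARG00000037533 lower (-6.30 ± 1.31, adjusted p = 0.0410). This pair was picked out after its values were seen.

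Transporters of peptides and amino acids were higher in LRE as a list, though 12 of the 31 listed symbols, the peptide transporters slc15a1a and slc15a1b among them, were not matched. Of 19 tested members, 7 were higher and 1 lower, or 11 and 2 when adjusted over the list alone (median 1.54, adjusted p = 2.2e-08, adjusted p = 0.151 with an estimated correlation). With the wider symbol matching, 32 members had a median of 0.82 (adjusted p = 6.6e-04), and the log2 ratios of their summed abundance were 0.66, -0.03 and 0.71 in the pairs of libraries numbered 1, 2 and 3, against 1.16, 0.18 and 1.42 for the 19. The neutral amino acid transporter gene SLC6A18 went from 5.62 ± 2.25 to 222 ± 109 CPM (5.31 ± 0.54, adjusted p = 0.0027). SLC7A9, the light chain of the cystine transporter, rose by 2.98 ± 0.34 (adjusted p = 0.0043), and the glutamate transporter gene SLC1A1 by 2.39 ± 0.36 (adjusted p = 0.0129). The lower member was SLC1A4 (-1.58 ± 0.33, adjusted p = 0.0443), picked out after its values were seen. SLC1A1 lost its call without IEC 1, IEC 2 or LRE 3 (adjusted p up to 0.0584) and with scaling by totals alone (0.0944).

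Genes of bile acid, vitamin and ileal transport were higher in LRE as a list. Of 19 tested members, 6 were higher and 1 lower, or 10 and 1 when adjusted over the list alone (median 1.24, adjusted p = 1.8e-05, adjusted p = 0.236 with an estimated correlation). The apical bile acid transporter gene SLC10A2 went from 55.5 ± 38.8 to 874 ± 272 CPM (3.98 ± 0.59, adjusted p = 0.0118). The gene of its basolateral counterpart, slc51a, rose by 2.80 ± 0.38 (adjusted p = 0.0082), and tcn2, which encodes a vitamin B12 carrier, by 2.35 ± 0.32 (adjusted p = 0.0087). The lower member, picked out after its values were seen, was the carotenoid-cleaving enzyme gene BCO1 (-1.65 ± 0.32, adjusted p = 0.0309). SLC10A2 lost its call without IEC 1 (0.0615) and rose by 4.64 without IEC 3; tcn2 lost its call without IEC 2 or IEC 3 (up to 0.0608), and slc51a with scaling by totals alone (0.0881).

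Among lists of lipid handling, fat absorption and cholesterol biosynthesis were lower and fatty acid oxidation higher; the differences between the lists were not tested. Of 30 tested genes of dietary fat absorption and lipoprotein assembly, 4 were lower and 1 higher, or 6 lower and 2 higher when adjusted over the list alone (median -0.66, adjusted p = 0.0039, adjusted p = 0.395 with an estimated correlation). Their summed abundance was about equal, with 4326 ± 795 CPM in IEC and 4296 ± 908 in LRE, and log2 ratios of -0.54, 0.41 and 0.09 in the pairs numbered 1, 2 and 3. FABP2, the intestinal fatty acid binding protein, had 1116 ± 445 CPM in IEC and 241 ± 80.1 in LRE (-2.21 ± 0.42, adjusted p = 0.0304). The apolipoprotein genes apoea (-2.54 ± 0.51, adjusted p = 0.0373) and apoc2 (-1.71 ± 0.35, adjusted p = 0.0376) fell too, whereas apoeb, picked out after its values were seen, rose by 1.62 ± 0.33 (adjusted p = 0.0409). The cholesterol biosynthesis list was lower (median -0.56, adjusted p = 0.0026, adjusted p = 0.236 with an estimated correlation), although DHCR7, the enzyme of the last step, was the only 1 of its 21 members to pass, also when adjusted over the list alone (-2.01 ± 0.31, adjusted p = 0.0132). In the list of fatty acid oxidation, 2 of 24 members were higher, or 12 when adjusted over the list alone, and none lower (median 0.69, adjusted p = 3.0e-06, adjusted p = 0.236 with an estimated correlation). These were CPT1B, the carnitine shuttle enzyme (4.07 ± 0.58, adjusted p = 0.0110), and the peroxisomal enzyme gene EHHADH (1.36 ± 0.29, adjusted p = 0.0458). The fat absorption list lost its call without LRE 2 (0.0907, median -0.42), and apoea fell by 3.16 without LRE 3. FABP2 and EHHADH lost theirs without any 1 of the 6 libraries (adjusted p up to 0.109 and 0.182), apoc2 in all leave-outs but that of IEC 2 (up to 0.124), apoea without IEC 1, IEC 3, LRE 1 or LRE 2 (up to 0.125) and DHCR7 without IEC 3, LRE 2 or LRE 3 (up to 0.0633), and scaling by totals alone ended the calls of apoea (0.0595), CPT1B (0.0621) and EHHADH (0.327).

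Sugar and xenobiotic metabolism were also higher. In the sugar list, 1 of 14 members passed, or 3 when adjusted over the list alone, all higher (median 0.70, adjusted p = 1.0e-04, adjusted p = 0.236 with an estimated correlation). It was SLC5A9, a sodium and sugar cotransporter gene (2.42 ± 0.35, adjusted p = 0.0110). Of 27 genes of xenobiotic metabolism, 4 were higher and none lower, or 8 higher and 2 lower when adjusted over the list alone (median 0.80, adjusted p = 5.2e-04, adjusted p = 0.236 with an estimated correlation; median 0.48 without IEC 1 and 0.29 without LRE 3). They included the cytochrome P450 gene cyp2k18 (3.01 ± 0.33, adjusted p = 0.0033), the glucuronosyltransferase gene ugt5a1 (2.75 ± 0.39, adjusted p = 0.0106) and the glutathione transferase gene gstr, which went from 226 ± 56.8 to 907 ± 226 CPM (adjusted p = 0.0252). These 3 families hold near-identical copies, and their values are uncertain to that extent. SLC5A9 lost its call without IEC 2 (0.0556), ugt5a1 without IEC 3 (0.0535) and gstr in all leave-outs but that of LRE 2 (up to 0.109), and all 3 lost it with scaling by totals alone (0.0963, 0.101 and 0.0943).

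Among genes of the microvillus, 1 of 16 was higher, or 3 when adjusted over the list alone, and none lower (median 0.61, adjusted p = 0.0147, adjusted p = 0.322 with an estimated correlation). It was PLS1, which encodes the actin bundler plastin 1 (1.78 ± 0.34, adjusted p = 0.0307). The list lost its call without LRE 1 (0.0683), without both libraries numbered 1 (0.111, median 0.25) and with scaling by totals alone (0.0732, median 0.12), and the log2 ratios of its summed abundance were 0.51, -0.21 and 0.12 in the pairs numbered 1, 2 and 3. PLS1 lost its call without any 1 of the 6 libraries (up to 0.121) and with scaling by totals alone (0.244). The list of intestinal transcription factors did not pass (median -0.12, adjusted p = 0.461). Of its 25 members, hoxa13b, a Hox gene of the posterior body, rose from 5.00 ± 1.17 to 48.5 ± 10.9 CPM (3.27 ± 0.33, adjusted p = 0.0027). The endodermal factor gene FOXA1 fell by 2.03 ± 0.33 (adjusted p = 0.0178), and lost its call without IEC 1, IEC 3, LRE 2 or LRE 3 (up to 0.0723). Adjusted over the list alone, 2 factors were higher and 3 lower. Neither innate immune genes (0 of 24, median -0.67, adjusted p = 0.0709) nor genes of iron, zinc and copper handling (0 of 17, median 0.08, adjusted p = 0.359) passed as lists or as single genes, also when adjusted over the list alone. The innate immune list was lower with the replicate block (0.0467), without IEC 3 (5.2e-04) and without LRE 2 (0.0120).

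**Figure D1:**
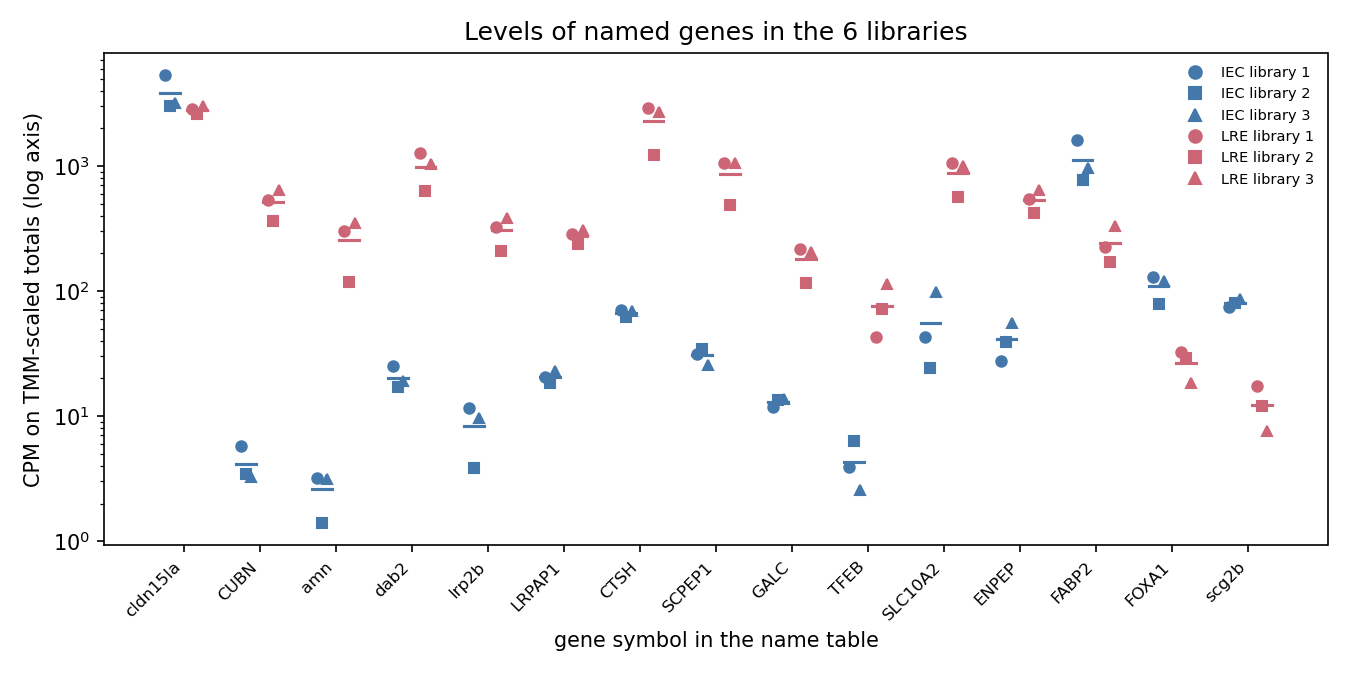
Abundance in CPM on a log axis for 15 genes in each of the 3 IEC and 3 LRE libraries; each point is 1 library, its shape the library number, and each horizontal line the mean of a group. CUBN lies at 3.24 to 5.77 CPM in IEC and at 366 to 640 CPM in LRE, whereas cldn15la lies at 3036 to 5298 CPM in IEC and at 2593 to 3011 CPM in LRE.

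Beyond these groups, the genes with the largest changes at a mean of at least 10 CPM included several without a described role here. The highest, mbd3b, had 0, 49 and 3 counts in the IEC libraries 1, 2 and 3 and 1983, 1917 and 2094 in the LRE libraries. Its ratio was 148, with a 95% interval of 113 to 199 that covers counting error only (adjusted p = 0.0122); it was 1465 (501 to 7107) without IEC 2 and 98.6 (74.5 to 133) without IEC 3, and the call ended without both libraries numbered 1 (0.0546). The sorting nexin gene SNX8 (ENSDARG00000074842) went from 1.72 ± 1.19 to 141 ± 47.0 CPM (6.35 ± 0.64, adjusted p = 0.0027) and tmem236 from 0.473 ± 0.0718 to 32.7 ± 11.9 CPM (6.11 ± 0.46, adjusted p = 0.0018). The uncharacterised si:ch73-338a16.3 rose by 6.50 ± 0.67 (adjusted p = 0.0029). In the other direction, the incretin hormone gene gip had 5189, 689 and 769 counts in IEC 1, 2 and 3 and 0, 1 and 3 in LRE, a ratio of 1292 with a 95% counting interval of 504 to 4744 (adjusted p = 0.0122). That ratio was 353 (138 to 1297) without IEC 1, 2031 (793 to 7457) without IEC 2 and 3277 (588 to 129446) without LRE 3. The hormone gene ghrl (ghrelin) fell from 397 ± 335 to 6.23 ± 7.02 CPM (adjusted p = 0.0288). The transcription factor gene SPIC fell by 4.45 ± 0.57 (adjusted p = 0.0066) and zgc:172120 by 4.42 ± 0.53 (adjusted p = 0.0049). The lectin gene jac7 fell by 6.08 ± 1.04 (adjusted p = 0.0206) and si:ch73-343g19.4 by 4.41 ± 0.89 (adjusted p = 0.0373). The calls of gip ended without LRE 2 or LRE 3 (up to 0.0565), of jac7 without IEC 1, IEC 3 or LRE 2 (up to 0.0881), and of ghrl and si:ch73-343g19.4 in all leave-outs but that of LRE 1 (up to 0.106 and 0.133); limma voom ended those of gip and jac7 (0.267 and 0.0753). Leaving out 1 library moved the fold by over 1.5 times for SNX8 (log2 6.98 without IEC 3), si:ch73-338a16.3 (7.28 without IEC 1), jac7 (-7.02 without LRE 3), ghrl (-6.00, or -5.06 without IEC 1 and -7.45 without LRE 1) and si:ch73-343g19.4 (-3.53 without IEC 1 and -5.11 without LRE 1). The gene with the most counts in any library, ENSDARG00000080337, had no symbol.

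Markers of enteroendocrine cells and of best4 and ion-secreting cells were lower in LRE, whereas those of goblet cells did not pass. In the list of enteroendocrine cells, which make gut hormones, 1 of 14 members passed and was lower, or 11 lower when adjusted over the list alone (median -2.58, adjusted p = 3.6e-09, adjusted p = 0.236 with an estimated correlation). The granule protein gene scg2b fell from 80.5 ± 5.90 to 12.3 ± 4.83 CPM (-2.71 ± 0.34, adjusted p = 0.0066). The most abundant member, insl5a, had 2994 ± 3805 CPM in IEC, 7384 of them in IEC 1, against 423 ± 417 in LRE, and did not pass (-2.82 ± 1.09, adjusted p = 0.229; 0.0401 with the replicate block). Of 8 markers of best4 and ion-secreting cells, 1 was lower, or 4 when adjusted over the list alone (median -1.60, adjusted p = 6.8e-04, adjusted p = 0.236 with an estimated correlation). It was the tachykinin receptor gene TACR2, which had 15.08 ± 5.81 CPM in IEC and 0.343 ± 0.460 in LRE (adjusted p = 0.0373) with a log2 fold change of -5.41, or -7.67 without LRE 2, and lost its call in all leave-outs but that of LRE 2 (up to 0.115) and with scaling by totals alone (0.0588). The carbonic anhydrase gene ca4b had 160 ± 58.2 CPM in IEC and 40.7 ± 27.4 in LRE (adjusted p = 0.0841; 0.0275 with the replicate block, 0.0363 with scaling by totals alone and 0.0298 without LRE 1). No goblet marker passed (0 of 10, also when adjusted over the list alone, list median -0.45, adjusted p = 0.211; 0.0436 without LRE 1).

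The list of intestinal epithelium did not pass either (median -0.24, adjusted p = 0.0818), with 1 of its 12 members lower, or 2 when adjusted over the list alone. It was lower with the replicate block (0.0203), with scaling by totals alone (0.0088), without IEC 2 (0.0401) and without IEC 3 (0.0270). Its lower member TM4SF5, a tetraspanin-like membrane protein, fell from 168 ± 66.9 to 26.6 ± 8.67 CPM (-2.66 ± 0.39, adjusted p = 0.0114; 0.0631 without LRE 3). The most abundant member, lgals2b, had 7325 ± 5987 and 5627 ± 2351 CPM (adjusted p = 0.821), with a log2 fold change of -0.38 that was 0.54 without IEC 1.

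Markers of cells outside the gut epithelium were present in both groups and several were higher in LRE. The epidermis list was higher (median 1.299, adjusted p = 1.2e-05, adjusted p = 0.236 with an estimated correlation), with 1 of 14 members higher, or 8 higher and 1 lower when adjusted over the list alone. Its keratinocyte factor gene TP63 rose by 1.80 ± 0.31 (adjusted p = 0.0206), but lost its call in all leave-outs but that of LRE 1 (up to 0.0920) and with scaling by totals alone (0.199). The keratin gene krt4 had 5920 ± 1455 CPM in IEC and 10628 ± 1726 in LRE (adjusted p = 0.383). No single gene passed in the lists of fibroblasts and endothelium (16 members, median 1.27, adjusted p = 8.7e-05, adjusted p = 0.269 with an estimated correlation), muscle (12, 1.09, 2.7e-04, adjusted p = 0.285 with an estimated correlation), hepatocytes (18, 1.01, 8.9e-04, adjusted p = 0.452 with an estimated correlation; median 0.59 without LRE 3) or neurons (10, 1.03, 0.0039, adjusted p = 0.236 with an estimated correlation), all higher as lists. Adjusted over the list alone, 5 fibroblast genes were higher, as were 4 neuronal genes, with 1 neuronal gene lower and none changed in muscle or hepatocytes.

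Leukocyte markers were lower (0 of 25 members, also when adjusted over the list alone, median -0.86, adjusted p = 0.0245, adjusted p = 0.607 with an estimated correlation). This call rested on IEC 2, without which the median was 0.56 and the adjusted p 0.818; it also ended without LRE 3 (0.174, median -0.52) and with scaling by totals alone (0.0900), and the median was -1.53 without LRE 2. Exocrine pancreas markers were lower (0 of 13, also when adjusted over the list alone, median -0.46, adjusted p = 0.0457, adjusted p = 0.649 with an estimated correlation). That call ended without IEC 1 (0.145), IEC 2 (0.180, median -0.30), LRE 1 (0.727, median 0.02) or LRE 3 (0.0911, median -0.28) and with scaling by totals alone (0.0923), and it turned without both libraries numbered 1 (0.976, median 0.22); the median was -0.83 without IEC 3 and -1.67 without LRE 2. Erythrocyte markers (0 of 7, median 0.26, mean -0.07, adjusted p = 0.644) and pronephros markers (0 of 8, median -0.18, adjusted p = 0.849) did not pass, also when adjusted over the list alone.

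**Figure D2:**
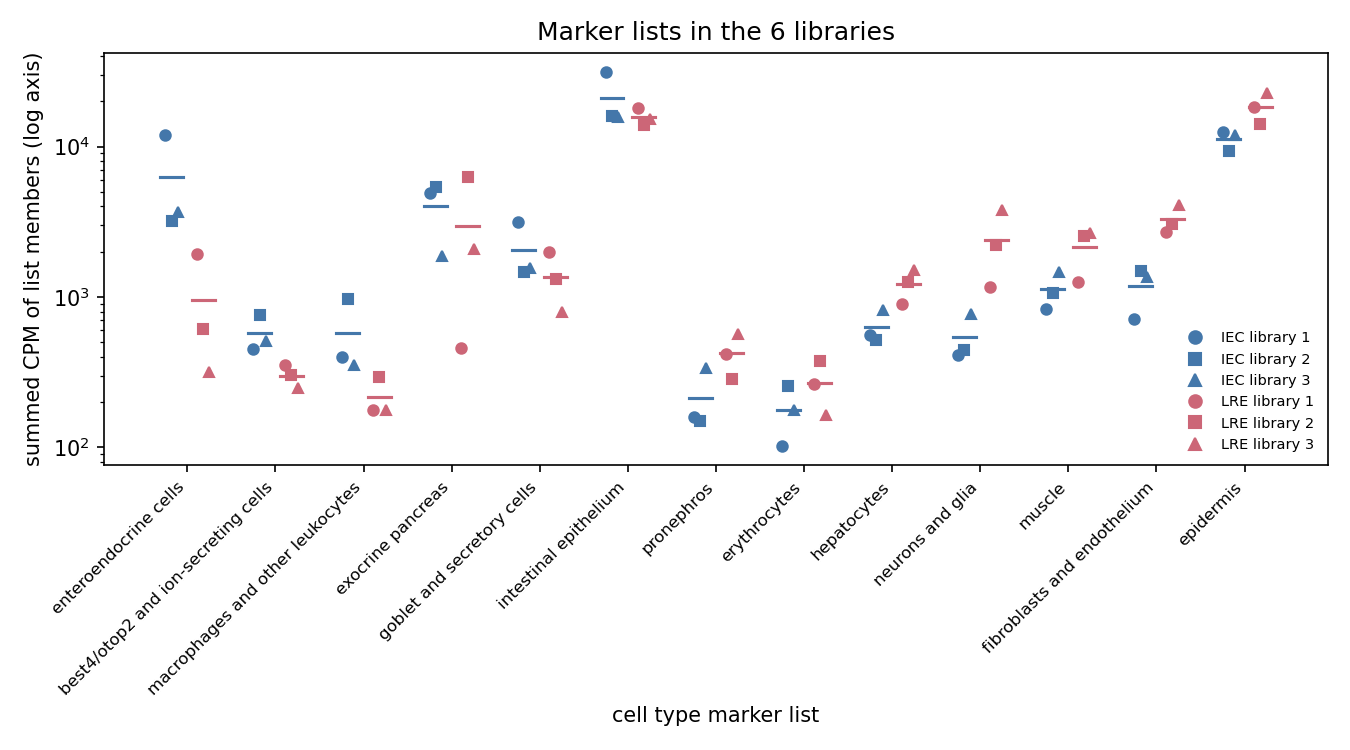
Summed abundance in CPM of the 13 marker lists in each library, on a log axis; each point is 1 of the 3 IEC or 3 LRE libraries, and each horizontal line the mean of a group. Leukocyte sums lie between 351 and 969 CPM in IEC and between 178 and 295 CPM in LRE, and enteroendocrine sums between 3218 and 11854 CPM in IEC and between 315 and 1944 CPM in LRE.

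Of the 4 quality lists, 2 differed. Proliferation genes were lower in LRE (0 of 25 members passed, also when adjusted over the list alone, median -0.74, adjusted p = 9.9e-05, adjusted p = 0.151 with an estimated correlation). Mitochondrially encoded transcripts were higher (0 of 13, also when adjusted over the list alone, median 1.47, adjusted p = 1.5e-04, adjusted p = 0.450 with an estimated correlation), a call that ended without LRE 1 (0.0606), where the median was 0.59, against 2.36 without IEC 1. The most abundant named gene in both groups, MT-CO1, had 14050 ± 7974 CPM in IEC and 39776 ± 34817 in LRE (adjusted p = 0.378). MT-CO2 and MT-CO3 were also among the 3 most abundant and did not pass (adjusted p = 0.436 and 0.370). The lists of dissociation and heat-shock response (0 of 22, median -0.36, adjusted p = 0.184) and of the unfolded protein response (0 of 21, median -0.34, adjusted p = 0.268) did not pass, also when adjusted over the list alone.

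In the lists where no gene passed with edgeR, an unadjusted p under 0.05 was reached by 9 proliferation and 4 leukocyte genes, all with lower values in LRE. It was reached by 7 fibroblast and endothelial, 6 hepatocyte, 5 muscle, 3 mitochondrial and 1 pronephros genes, all with higher values. Metal handling (3 with higher values, 1 with lower), neurons (4 and 1), innate immunity (1 and 3) and goblet cells (1 and 2) were mixed. The dissociation and unfolded protein lists had 2 each and exocrine pancreas 1, with lower values, and erythrocytes 0. DESeq2 called 5 fibroblast and endothelial, 4 neuronal, 3 metal-handling, 1 hepatocyte and 1 mitochondrial genes higher, and 4 proliferation, 3 innate immune, 2 leukocyte, 1 neuronal, 1 pancreas and 1 unfolded protein genes lower. Of these lists, limma voom called 2 fibroblast and endothelial genes and 1 neuronal gene higher, and 1 neuronal and 1 pancreas gene lower.

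**Figure D3:**
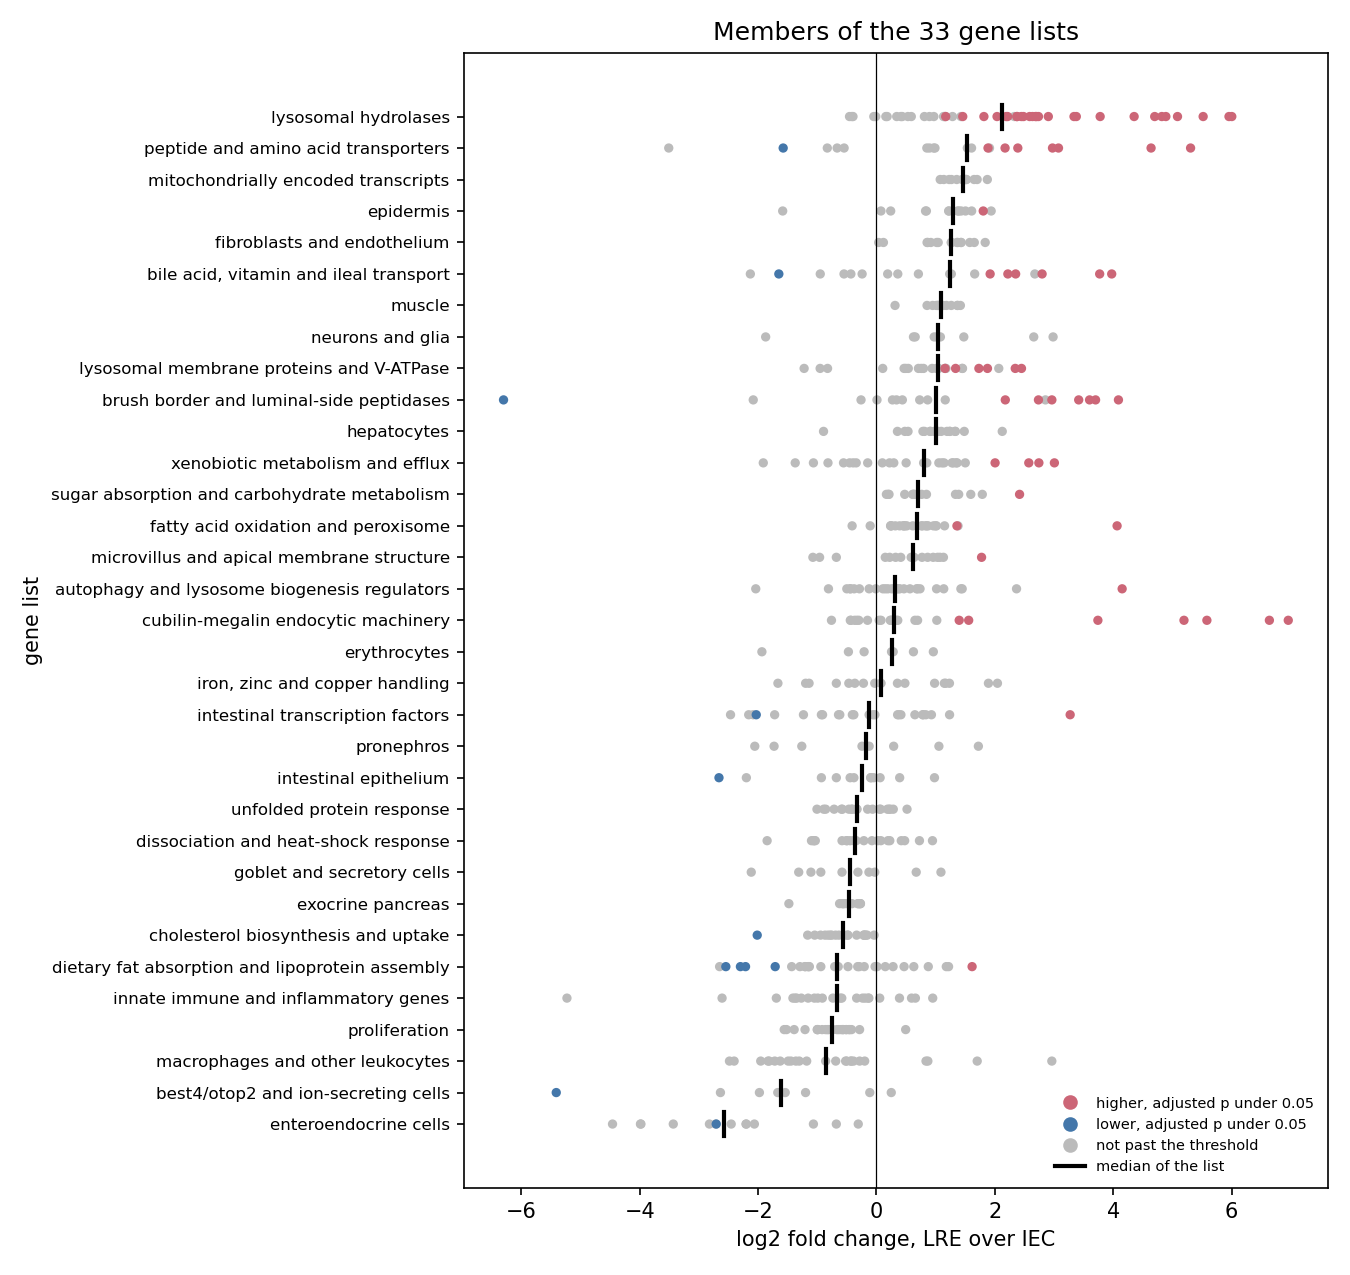
Log2 fold change, LRE over IEC, of each tested member of the 33 lists; red points passed as higher, blue as lower, grey points did not pass, and the black bar is the median of a list. The lysosomal hydrolases have a median of 2.11 with 27 of 48 members in red, and the enteroendocrine markers a median of -2.58.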

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

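The alternatives changed the counts of genes. No gene of the main fit passed in the opposite direction in another fit, which says little because the fits share most or all of their libraries. Chosen after seeing the data were 4 alternatives: the fit without mitochondrial and top genes, the fit without both number 1 libraries, the robust fit and the wider symbol matching. Against 483 genes higher in LRE, totals-only scaling gave 137, DESeq2 1316, the replicate block 789, the fit without both number 1 libraries 251, and the leave-outs of 1 library 146 to 419. Against 191 lower, DESeq2 gave 952, limma voom 290, the block 367 and the leave-outs 28 to 261. For TREAT, against 153 higher, totals-only scaling gave 49, the fit without both number 1 libraries 28, and the leave-outs 55 to 117. Against 33 lower, it gave 68 with no filter, 60 with the block, 15 without both number 1 libraries and 3 to 75 in the leave-outs. Of the 17 lists higher and 7 lower, 0 and 0 passed with an estimated correlation and 10 and 3 with fry, while the leave-outs gave 14 to 17 higher and 5 to 9 lower. The cause was not tested, except that leave-outs and the fit without both number 1 libraries have fewer libraries.

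Blocking on the number moved the counts above, brought the innate immune and intestinal epithelium lists and the genes ca4b and insl5a past the threshold, and changed no other list or named gene. Of the 48 named genes that passed, 25 passed in all 6 leave-outs, 19 lost their call in 1 to 5 of them and 4 in all 6. Totals-only scaling ended 14 of these calls and the fit without both number 1 libraries 17. The exocrine pancreas list, which passed as lower (median -0.46, adjusted p = 0.0457), turned without both number 1 libraries (0.22, adjusted p = 0.976), and medians of lists that passed turned while their tests kept their direction: leukocytes without IEC 2 (0.56), exocrine pancreas without LRE 1 (0.02), and the endocytic machinery (-0.12) and autophagy regulators (-0.07) with totals-only scaling, which moved the median of all genes by -0.40. The other turns were in results that had not passed, and the cause was not tested. The log2 fold change of lgals2b (-0.38) ran from -0.76 to 0.54 over the leave-outs, with 0.54 without IEC 1, and was 0.19 without both number 1 libraries. The erythrocyte list (median 0.26) ran from -0.51 to 0.65, turned without IEC 1 (-0.09), without LRE 2 (-0.51) and without both number 1 libraries (test down, median 0.075). The pronephros list (-0.18) ran from -2.06 to -0.22 and turned with totals-only scaling (test up, median -0.50), the CPM filter (0.31), wider matching (0.57), without LRE 1 (test up, -0.22) and without both number 1 libraries (test up, -0.25). Thinning to the smallest total gave 494 genes higher and 196 lower, so depth did not limit the counts in that range; lower depths were not tried. In simulation, 2% of 2-fold changes were recovered among genes above a minimum abundance.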

Other observations

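The questions, gene groups and comparisons in this part were chosen after the results were seen. The 33 gene lists, camera, fry, the estimated correlation and the leave-outs of 1 library that they draw on were fixed in advance. The kynurenine, Hox and Notch groups were picked because their members passed, so no test of a group as a whole is given. Of 12 tested genes of tryptophan breakdown along the kynurenine pathway, 5 passed, all higher in LRE, and 7 with the replicate block. The first enzyme of the pathway, tdo2b, went from 20.1 ± 10.5 to 973 ± 287 CPM (log2 fold change 5.59 ± 0.53, edgeR adjusted p = 0.0024), and KMO (3.17), kynu (2.27), HAAO (3.41) and TDO2 (3.77) passed too. Among Hox genes of the most posterior group, 13, 4 of 5 were higher, namely hoxa13a (2.41), hoxa13b (3.27), HOXC13 (2.61) and hoxd13a (3.02), and of 16 genes of groups 9 to 12 HOXC12 passed (1.99); the difference between these groups was not tested. Of 28 Notch ligand and Hes or Her factor genes, 7 were lower and none higher, including DLL1 (ENSDARG00000020219, -3.01), her15.2 (-3.11) and HES1 (-2.07). Her genes include close copies, so their single values are uncertain.

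A search covered 704 families of symbols in both directions (1408 one-sided Fisher tests). Of all 19289 genes with a symbol, 454 were higher and 180 lower. Solute carriers were more often higher than all genes (SLC, 36 of 399, adjusted p = 7.9e-09, with 6 of the 399 lower), as were thrombospondins (THBS, 4 of 8, 0.0069). More often lower were HES (3 of 5, 0.0037), TOX (3 of 5, 0.0037) and FABP genes (3 of 11, 0.0351). These tests treat genes as independent, and no correlation between genes was allowed for. FABP6, the ileal bile acid binding protein, went the other way, from 649 ± 359 to 8865 ± 3824 CPM. Of 1300 symbols carried by several tested genes, 12 had more than 1 that passed, and in 4 these went in opposite directions. Among them, MYO6, an actin motor of endocytosis, was higher for ENSDARG00000044016 (2.297 ± 0.264, adjusted p = 0.0042) and lower for ENSDARG00000042141 (-2.18 ± 0.36, adjusted p = 0.0190).

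The endocytic and lysosomal genes that are higher in LRE are also abundant in macrophages and kidney tubules, so other cells that took up the tracer could be their source, although the gate on GFP should remove both. Leukocytes as a whole are argued against as the source, since they would bring their abundant transcripts along. The sum of their markers was 295 CPM in the highest LRE library and 351 in the lowest IEC library, although NCF1 alone had 170 CPM in IEC and 68.9 in LRE. With the wider symbol matching these sums lay closer together, at 356 and 372 CPM. The log2 ratios of the sums were then -1.07, -1.60 and -0.94 in the pairs numbered 1, 2 and 3. The list pools macrophages with other leukocytes, and macrophage markers were not summed apart, so macrophages alone stay open. The less abundant leukocyte markers vary more: the median difference over all 25 was 0.35, -1.41 and -0.99 on the log2 scale in the pairs numbered 1, 2 and 3, and the median log2 fold change was 0.56 without IEC 2, where the positive values lie below the 2.11 of the hydrolases. Tubule cells cannot be told apart, because of 21 tested pronephros genes (wider symbol matching, median 0.57, SD 1.498) 11 had under 1 CPM in IEC, near the floor, 5 had over 10 CPM, where a small share would be hidden, and of those between only 4 mark tubules, since podxl marks podocytes. Of the 5 over 10 CPM, SLC4A4 (ENSDARG00000013730) passed as higher, from 36.4 to 197 CPM (2.44 ± 0.37, edgeR adjusted p = 0.0127), and the others did not pass. The summed abundance of the 21 genes had log2 ratios of 1.25, 0.76 and 0.80 in the pairs numbered 1, 2 and 3. As a list they were just short of the threshold as higher (camera adjusted p = 0.0530). A program of the lysosome rich enterocytes, which the design names, stays open and was not tested separately.

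Epidermal, fibroblast, muscle, hepatocyte and neuronal markers were all higher in LRE, which could come from a lower share of intestinal cells in the sort, although the gate on GFP should remove them. A plain dilution would raise every other cell type alike, but the log2 ratio of summed leukocyte markers was -1.29 ± 0.38 (mean ± SD of 3 pairs) and that of the lowest of the 5 lists, epidermis, 0.70 ± 0.20. The median differences of leukocyte members, 0.35, -1.41 and -0.99, also lay below the lowest of the 5 lists in each pair (0.95, 0.62 and 0.72), although the leukocyte median was 0.56 without IEC 2. With the wider symbol matching, pair 1 went the other way, with a median difference of 0.391 for leukocytes and 0.375 for neurons, while pairs 2 and 3 kept the order. LRE library 1 alone is argued against too, since 5 of the 5 lists stayed higher without it (camera at the preset correlation, highest adjusted p = 0.0021), although with all libraries none passed with an estimated correlation (0.236 to 0.452) and only epidermis with fry. Of the markers, 14 of 14 epidermal, 14 of 16 fibroblast, 12 of 12 muscle, 17 of 18 hepatocyte and 9 of 10 neuronal genes have at least 1 CPM in IEC, and the most abundant in IEC of the first 4 lists were krt4, col1a1a (623 CPM in IEC and 1616 in LRE), TAGLN (354 and 440) and RBP4 (185 and 437). A larger admixture of particular cell types, or of free RNA from them, stays open and was not tested, as does expression of these genes by the enterocytes.

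Enteroendocrine and best4 markers were lower in LRE. An equal loss of every other epithelial type would lower both lists alike, if each marks its cells alone. Enteroendocrine medians lay below goblet medians in all 3 pairs of equal number, by -2.12 on average on the log2 scale (SD 0.30). Whether other cells also make the listed goblet genes was not tested, so these values do not settle whether the loss was equal. IEC library 1, which held most insl5a, is not the whole cause, since both lists (2 of 2) stayed lower without it (camera at the preset correlation, highest adjusted p = 2.6e-05), although with all libraries neither passed with an estimated correlation (0.236 for both), nor best4 with fry (0.0536). That the gate on dextran may leave out enteroendocrine cells more than goblet cells stays open and was not tested.

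The 6 libraries can be split into 2 groups of 3 in 10 ways, which cannot give a share under 0.05. The real split, 1 of the 10, gave 674 genes, and the highest of the other splits 0. For changes beyond 2-fold the values were 186 and 0, and for gene lists 24 and 19. Among the 4 splits that part all 3 pairs of equal number, the highest other values were 0 genes and 16 lists.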
